A study of Mus musculus with 8 samples.

How the data were processed

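Bulk RNA sequencing was done on total RNA from liver of male C57BL6 mice, extracted with Trizol, per the labels. The comparison is that of 5 AKT_NICD_ICC libraries with 3 WT libraries, grouped as the labels give them. Reads were trimmed with Trimmomatic 0.38 and aligned with STAR 2.6.1a to the mm10 build, per the submitters' processing notes. The deposited values are raw counts per gene from STAR, as whole numbers for 24411 gene symbols in each library. The gene annotation is not given in the sources used here, and no mitochondrial genes are among the symbols, so a mitochondrial share was not computed.

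The unstranded counts (column 2) were used, since the strand columns held near equal counts (50.3% in the first strand column for ICC) and the rule asked for at least 80% on 1 strand. Unmapped, multimapping, ambiguous and unassigned reads were kept out of library sizes and tests and are reported as shares. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 14307. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, group as the 1 factor), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are TMM-scaled. Genes at 0 in all WT libraries are given as at least N-fold higher, against a floor of 3 counts over the WT group, and genes with 1 to 3 WT counts as a ratio of counts with a 95% counting interval.

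In each of 34 gene lists members that rose or fell were counted, by the adjustment over all genes and adjusted over the list alone. The 31 lists with at least 3 tested genes were tested with limma 3.58.1: camera on log-CPM (prior count 2) with an inter-gene correlation preset at 0.01 and, as the alternative, estimated per list, and fry as a test that compares no other genes. Shares of reads were compared by an exact permutation test over all 56 splits of the 8 libraries. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise.

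Genes are named by a rule with 3 parts. The first is 20 fixed genes of the Notch, AKT, Hippo, DNA methylation, biliary and hepatocyte groups. The second is the 5 largest changes in each direction among genes that passed, with groups that did not overlap, a mean of at least 10 CPM in the higher group and a symbol that is not a model name. The third is, for each list, the 2 members with the smallest adjusted p in the direction most passing members took and the 1 with the smallest adjusted p in the other direction. Genes outside the rule were chosen after their values were seen and include Rn45s, Lars2, Mir6236 and Umod. Coordinates are GRCm38.

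The fit was tested on simulated counts for this comparison, over 14191 genes with 100 genes planted at 2-fold and 100 at 4-fold. edgeR recovered 64% of the 2-fold genes and 98.0% of the tested 4-fold genes and called 4 unplanted genes. In the same simulation camera found the planted list (adjusted p = 4.77e-33, or 0.00035 with an estimated correlation) and 0 of 30 random lists. Apart from the planted genes both simulated groups had the same mean profile, and each gene was drawn independently. The simulation therefore does not test the scaling between groups as unlike as the real ones, or the correlation between real genes.

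The alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no count filter, at least 10 counts in each library of a group, the larger strand column, thinning to the smallest library, the replicate number as a block, leaving out each library in turn, and the estimated inter-gene correlation. An alternative without Rn45s, Lars2 and Mir6236 was chosen after seeing the data. No 2 libraries were near copies of each other (lowest chi-square per degree of freedom between 2 libraries of a group 16.0).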

Results

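RNA was measured by bulk sequencing in 8 mouse liver samples, all from C57BL6 males aged 2 months on regular chow. The 3 WT libraries came from healthy control liver. The 5 AKT_NICD_ICC libraries, called ICC libraries here, came from liver with intrahepatic cholangiocarcinoma, a cancer with features of bile duct cells, in a model named for human AKT, a kinase that promotes growth, and NICD, the intracellular and active part of a NOTCH receptor. Gene counts summed to 16792925, 16924193 and 13116709 in WT replicates 1 to 3 and to 18958152, 22460869, 17140812, 27009951 and 17918029 in ICC replicates 1 to 5. At that depth 3 counts were worth 0.249 to 0.335 CPM in a WT library and 0.101 to 0.137 CPM in an ICC library. The labels do not say that the replicates were separate animals, so p-values measure the spread between these samples, which could be technical in part. Counting intervals and floors cover counting error only.

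The comparison asks which transcripts differed between healthy liver and the NICD and AKT tumour model, and the series title names NOTCH, YAP1 with its TEAD partners, and DNMT1 as the genes of interest in the change of hepatocytes into cholangiocarcinoma. Of the tested members of fixed gene lists, 23 of 25 biliary markers, 20 of 20 mitosis genes and 7 of 10 Notch target genes rose in the ICC libraries, and 15 of 16 genes of the urea cycle and amino acid catabolism fell. These 4 lists passed camera at a preset inter-gene correlation, with adjusted p of 1.68e-07, 4.86e-09, 0.0259 and 6.39e-06, and not with an estimated correlation, with adjusted p of 0.38, 0.38, 0.38 and 0.412. The biliary transcription factor Sox9 went from 7.76 ± 1.57 CPM (SD, n = 3) in WT to 191 ± 27.1 CPM (SD, n = 5) in ICC, a log2 fold change of 4.61 (SE 0.20, edgeR adjusted p = 1.92e-07). Alb, which encodes albumin, went from 102951 ± 13763 to 34786 ± 11043 CPM, a log2 fold change of -1.57 (SE 0.44, edgeR adjusted p = 0.01). Dnmt1, the maintenance DNA methyltransferase, rose from 18.5 ± 2.11 to 57.9 ± 5.39 CPM, whereas Yap1 went from 123 ± 14.2 to 86.9 ± 16.5 CPM, a fall (adjusted p = 0.0183) whose call was lost with upper-quartile scaling, in the larger strand column and without WT replicate 2 (adjusted p = 0.0532, 0.0547 and 0.0888), and which total counts turned to a rise of 0.31 (adjusted p = 0.0470).

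Of 24411 genes in the files, 14307 passed the count filter, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5423 higher and 4368 lower in ICC. Changes over 2-fold numbered 3856 higher and 2131 lower. Among all 14307 genes tested, called or not, every ICC library lay above every WT library in 5297 and below every WT library in 4344, which chance gives for 1.79% of genes per direction. Among the higher genes, 417 had 0 counts in all 3 WT libraries. The split between directions depended on the scaling of library sizes. It was 55.4% higher and 44.6% lower with TMM scaling, whose factors were 0.684 to 0.713 in WT and 1.10 to 1.37 in ICC, and 85.8% higher and 14.2% lower (9699 and 1601 genes) with total counts alone. The median log2 fold change of all genes tested was 0.11 with TMM scaling and lay 0.82 higher with total counts, 0.15 higher with upper-quartile scaling and 0.19 higher without the count filter. The first principal component held 89.2% of the variance and parted the groups. Correlations of log2 CPM were 0.982 to 0.984 within WT, 0.940 to 0.986 within ICC and 0.726 to 0.830 between groups.

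Of 10 tested Notch target genes 7 rose, 1 fell and 2 did not pass, with a median log2 fold change of 4.02, midway between Hes1 and Hey1, and of 2.58 without the count filter. The camera test gave an adjusted p of 0.0259 at the preset correlation and an adjusted p of 0.38 with an estimated correlation, and total counts alone ended the call (adjusted p = 0.217). Nrarp, which encodes a feedback inhibitor induced by Notch (chromosome 2, 25180758 to 25183339, GRCm38), rose from 2.91 ± 0.963 to 804 ± 203 CPM, a log2 fold change of 8.09 (SE 0.37, edgeR adjusted p = 2.27e-07). Heyl, Hey1 and Hes1, transcriptional repressors of the HES and HEY family, rose by log2 fold changes of 6.63, 5.48 and 2.56. For Hey1 the value was 6.57 without WT replicate 1, which held most of its WT signal (1.02 CPM against 0.249 and 0.223). Hes6, a relative of Hes1, fell by 2.14 on the log2 scale. Lfng and Bcl6, named after their values were seen, had log2 fold changes of 0.59 (adjusted p = 0.0783) and -0.41 (adjusted p = 0.340). Notch1 itself (chromosome 2, 26457902 to 26503822) rose from 33.7 ± 3.56 to 224 ± 69.2 CPM, a log2 fold change of 2.73 (SE 0.26, adjusted p = 1.05e-05), and Akt1 rose by 1.02 (SE 0.13, adjusted p = 6.92e-05). The tables give 1 count per gene symbol, so transcripts of an introduced Notch or AKT sequence cannot be separated from those of the mouse genes.

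Among Notch receptors, ligands and mediators, 10 of 20 tested members rose and 4 fell, and the list as a whole did not pass (camera adjusted p = 0.227, median 0.73). The ligand Jag1 rose by 3.42 (SE 0.16, adjusted p = 2.68e-07) and the receptor Notch3 by 4.22 (SE 0.37, adjusted p = 6.93e-06). Psen2, a catalytic part of the gamma-secretase that cuts Notch receptors, fell by 2.39 on the log2 scale (SE 0.24, adjusted p = 1.54e-05). Counts adjusted over the list alone were the same for both Notch lists.

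Genes of a YAP and TEAD target signature were mostly higher, while the signature's namesakes went different ways. Of 21 tested targets, 14 rose, 1 fell and 6 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 1.56, with a camera adjusted p of 0.0112 at the preset correlation and an adjusted p of 0.38 with an estimated correlation. Ajuba, which encodes a LIM protein, rose by 3.00 (SE 0.17, adjusted p = 5.36e-07), and Myof, which encodes a membrane protein, rose by 4.56 (SE 0.30, adjusted p = 1.38e-06). Asap1 fell by 0.55 on the log2 scale (adjusted p = 0.00423), and its sign turned with total counts (0.28). Yap1 (chromosome 9, 7931999 to 8004638) fell by 0.50 (SE 0.16, adjusted p = 0.0183). That call was lost with upper-quartile scaling (-0.35, adjusted p = 0.0532), in the larger strand column (-0.40, adjusted p = 0.0547) and without WT replicate 2 (-0.40, adjusted p = 0.0888), and total counts gave a rise of 0.31 (adjusted p = 0.0470). Wwtr1, which encodes the YAP relative TAZ, rose by 0.72 (SE 0.12, adjusted p = 0.000397). Of the TEAD transcription factors, Tead1 rose from 10.8 ± 2.33 to 64.3 ± 11.8 CPM (2.58, SE 0.20, adjusted p = 3.35e-06) and Tead2 from 1.10 ± 0.742 to 35.8 ± 12.4 CPM (5.08, SE 0.48, adjusted p = 1.05e-05). Tead3 had a log2 fold change of -0.26 (adjusted p = 0.133), which turned to 0.57 with total counts. Tead4 stayed under 1.1 CPM in each library, with a log2 fold change of 0.94 (adjusted p = 0.203) that passed without WT replicate 2 (2.44, adjusted p = 0.0142) and with total counts (1.75, adjusted p = 0.0269). Over all 18 Hippo pathway components 9 rose, 2 fell (Yap1 and Mob1b) and 7 did not pass, and the list did not pass (median 0.43, camera adjusted p = 0.227). Mob1b fell by 0.41 on the log2 scale (adjusted p = 0.00559) and was higher by 0.41 with total counts. Counts adjusted over the list alone were again the same.

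The DNA methylation list did not pass as a whole (median 0.32, camera adjusted p = 0.277). Of its 15 tested members 8 rose and none fell by edgeR's test, and 7 rose when adjusted over the list alone. Dnmt1 (chromosome 9, 20907206 to 20959888) had a log2 fold change of 1.64 (SE 0.12, adjusted p = 2.46e-06), and Uhrf1, which guides Dnmt1 to newly copied DNA, rose by 5.67 (SE 0.29, adjusted p = 3.73e-07), from 0.930 ± 0.177 to 46.9 ± 11.2 CPM. Dnmt3a, a de novo methyltransferase, rose by 0.50 (SE 0.12, adjusted p = 0.00369). Dnmt3b, the other de novo enzyme, had a log2 fold change of -0.57 (SE 0.25, adjusted p = 0.0684). It passed without ICC replicate 5 (-0.67, adjusted p = 0.0454) and was 0.25 with total counts (adjusted p = 0.377).

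**Figure D1:**
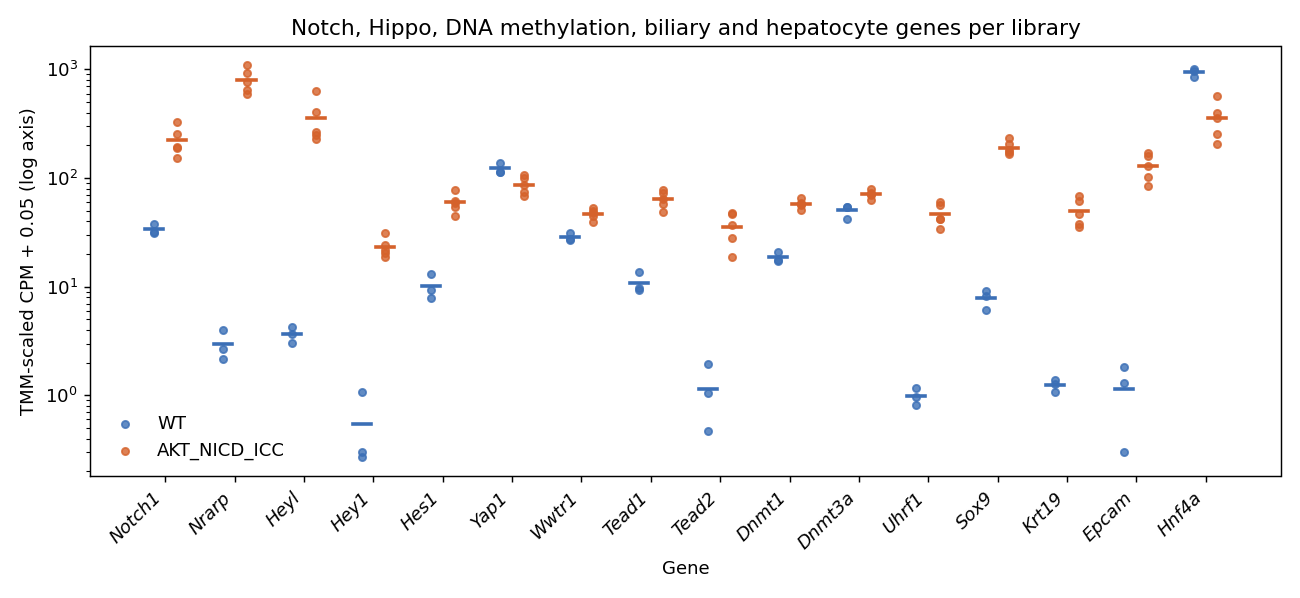
TMM-scaled CPM plus an offset of 0.05, on a log axis, for 16 genes of the Notch, Hippo, DNA methylation, biliary and hepatocyte groups; points are libraries (blue WT, orange AKT_NICD_ICC) and bars are group means. Each of these genes passed the edgeR test, with Yap1 and Hnf4a lower and the other 14 higher in ICC; Yap1 turned to a rise with total-count scaling.

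Biliary markers had the highest median of the 31 lists tested: 23 of 25 tested members rose, 1 fell and 1 did not pass, also when adjusted over the list alone. Their median log2 fold change was 5.81, or 5.62 with the member at 0 counts in WT set at its lower bound (camera adjusted p = 1.68e-07 at the preset correlation, adjusted p = 0.38 with an estimated correlation). Besides Sox9, Krt19, a keratin of bile duct epithelium, rose by 5.38 (SE 0.32, adjusted p = 8.15e-07) and Epcam, an epithelial adhesion molecule, by 6.94 (SE 0.46, adjusted p = 1.49e-06). The transcription factors Sox4 and Elf3 rose by 5.81 and 5.16, with adjusted p of 1.32e-07 and 1.43e-07. Aqp1, a water channel of bile ducts and also of endothelium, fell by 1.02 on the log2 scale (adjusted p = 0.00140), a call lost with total counts (-0.21, adjusted p = 0.308). Cldn3, named after its values were seen, had a log2 fold change of 0.20 (adjusted p = 0.292).

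The 5 largest rises were all of genes with 0 counts in WT. Gp2 (chromosome 7, 119442537 to 119459272), which encodes a zymogen granule membrane glycoprotein, reached 1824 ± 749 CPM (SD, n = 5), at least 19974-fold higher than the floor of 3 counts over the WT group (0.0913 CPM). Against the same floor Igfbpl1 (chromosome 4, 45809507 to 45826827), an insulin-like growth factor binding protein relative, was at least 6054-fold higher, and Grik3 (chromosome 4, 125490259 to 125714173), a glutamate receptor subunit, at least 3835-fold higher. Hs6st2 (chromosome X, 51386637 to 51681705), a heparan sulfate sulfotransferase, was at least 2531-fold higher, and Upk3a (chromosome 15, 85017141 to 85022560), a uroplakin of urothelium, at least 1816-fold higher. Their edgeR adjusted p lay between 1.92e-07 (Grik3) and 2.28e-06 (Hs6st2).

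The 5 largest falls were those of Clec2h, Hamp2, Hsd3b5, Car3 and Pitx3. Clec2h, a C-type lectin gene (chromosome 6, 128662385 to 128677374), went from 64.1 ± 26.2 to 0.227 ± 0.299 CPM, a log2 fold change of -8.18 (SE 0.59, adjusted p = 2.12e-06), which was -9.06 without ICC replicate 5. Hamp2, a hepcidin gene, had a log2 fold change of -6.93 (SE 0.34, adjusted p = 3.00e-07), and Hsd3b5, a steroid dehydrogenase of male liver, -6.80 (SE 0.97, adjusted p = 0.000152). With limma-voom Clec2h was at -9.12, Hsd3b5 at -8.02, Car3 at -7.58 and Pitx3 at -7.44. Car3, a carbonic anhydrase, went from 5275 ± 878 to 53.5 ± 56.5 CPM (-6.62, SE 1.02, adjusted p = 0.000254), and the homeobox gene Pitx3 from 13.7 ± 4.50 to 0.127 ± 0.185 CPM (-6.56, SE 0.66, adjusted p = 1.61e-05). Without ICC replicate 4 these were -7.44 for Car3 and -7.89 for Pitx3. Clec2h, Hamp2 and Hsd3b5 have close relatives in the genome, so reads that match more than 1 of them could be missing from their counts.

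Of 22 hepatocyte secreted proteins and transcription factors, 21 fell and Trf, named after its values were seen, did not pass (-0.92, adjusted p = 0.0598), while all 22 fell when adjusted over the list alone. Their median log2 fold change was -1.84 (camera adjusted p = 4.00e-07 at the preset correlation, adjusted p = 0.449 with an estimated correlation). Hnf4a, a master regulator of hepatocyte genes, fell by 1.40 (SE 0.29, adjusted p = 0.00163), and the nuclear receptors Nr1h4 (FXR) and Nr1i3 (CAR) had log2 fold changes of -1.44 and -1.51. In urea cycle and amino acid catabolism 15 of 16 tested genes fell, with a median of -2.25 (camera adjusted p = 6.39e-06, adjusted p = 0.412 with an estimated correlation). Among them Hal, which degrades histidine, fell by 3.52 and Tdo2, which degrades tryptophan, fell by 2.46. Of 16 drug-metabolising cytochrome P450 genes 15 fell, with a median of -2.67 (camera adjusted p = 6.72e-06, adjusted p = 0.412 with an estimated correlation). Cyp2c37 and Cyp2c54 had log2 fold changes of -3.13 and -3.29, although reads shared among these close paralogs make the single values uncertain. Of 15 genes for bile acid synthesis and transport 14 fell, with a median of -2.66 (camera adjusted p = 1.78e-05, adjusted p = 0.449 with an estimated correlation). The bile acid uptake transporter Slc10a1 fell by 2.87 and the canalicular exporter Abcc2 fell by 1.80. Ass1, of the urea cycle, had 3 counts over the WT and 0 over the ICC libraries and was not tested, which says that the counting did not measure it, and the same holds for Eno1 of glycolysis (0 and 1) and Tdg of DNA methylation (0 and 2). The exceptions in these 3 lists, named after their values were seen, were Sds (-0.69, adjusted p = 0.141), Cyp3a11 (-0.47, adjusted p = 0.475) and Cyp7a1 (-0.01, adjusted p = 0.988), the rate-limiting enzyme of bile acid synthesis.

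All 8 gluconeogenesis genes fell, with a median of -1.39 (camera adjusted p = 0.00161, adjusted p = 0.38 with an estimated correlation). G6pc, the catalytic subunit of glucose-6-phosphatase, fell by 3.68 (SE 0.42, adjusted p = 3.59e-05), and Gpt, alanine aminotransferase, fell by 1.82 (SE 0.16, adjusted p = 8.17e-06). In fatty acid oxidation and ketogenesis 14 of 16 genes fell and 1 rose, with a median of -1.53 (camera adjusted p = 1.26e-05, adjusted p = 0.38 with an estimated correlation). Cpt2, of the mitochondrial carnitine shuttle, fell by 1.96 and the peroxisomal enzyme Ehhadh fell by 1.84. Cyp4a14, a fatty acid omega-hydroxylase, had a log2 fold change of 1.66 (adjusted p = 0.0335) that rested on ICC replicate 3, at 429 CPM against 71.8 to 113 CPM in the other 4 ICC libraries. It was 0.87 (adjusted p = 0.00667) without that library, and the call was lost without WT replicate 1, 2 or 3 (adjusted p = 0.0602, 0.117 and 0.0788). In the pericentral zone list, of hepatocytes around the central vein, 7 of 10 genes fell and 1 rose, with a median of -1.14 (camera adjusted p = 0.0324, adjusted p = 0.449 with an estimated correlation). The glutamate transporter Slc1a2 fell by 1.62 and the ammonium transporter Rhbg fell by 1.58, whereas Slc1a4, a transporter of neutral amino acids, rose by 2.72. Counts adjusted over the list alone were the same for the urea cycle, P450, bile acid, gluconeogenesis, fatty acid oxidation and pericentral lists.

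All 12 male-biased liver genes fell, also when adjusted over the list alone. Their median log2 fold change of -3.78 was the lowest of the 31 lists tested (camera adjusted p = 0.000105 at the preset correlation, adjusted p = 0.449 with an estimated correlation). Mup3, a major urinary protein gene, fell by 3.98 (SE 0.47, adjusted p = 4.45e-05) and Cyp2d9 fell by 2.33 (SE 0.25, adjusted p = 2.08e-05), and both belong to families of near-identical genes whose reads can be shared. Of 12 female-biased genes 4 passed the count filter and 1 rose, and the list did not pass (camera adjusted p = 0.614). Its median of 2.21 ranged from 0.40 to 2.58 when single libraries were left out, with 0.40 without ICC replicate 3, 0.58 without ICC replicate 1, 0.61 without ICC replicate 5, 0.65 without WT replicate 3 and 0.78 without WT replicate 2. It was 0.49 to 0.51 with no filter, the stricter filter, the larger strand column and thinned libraries. Hao2, a hydroxyacid oxidase, rose to 2.40 ± 2.19 CPM from 5 WT counts, all in WT replicate 1 (3.94, adjusted p = 0.0160). The call was lost without WT replicate 2 (3.32, adjusted p = 0.0616) or 3 (3.47, adjusted p = 0.0554), and without WT replicate 1, with 0 WT counts left, it was at least 16.8-fold higher.

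**Figure D2:**
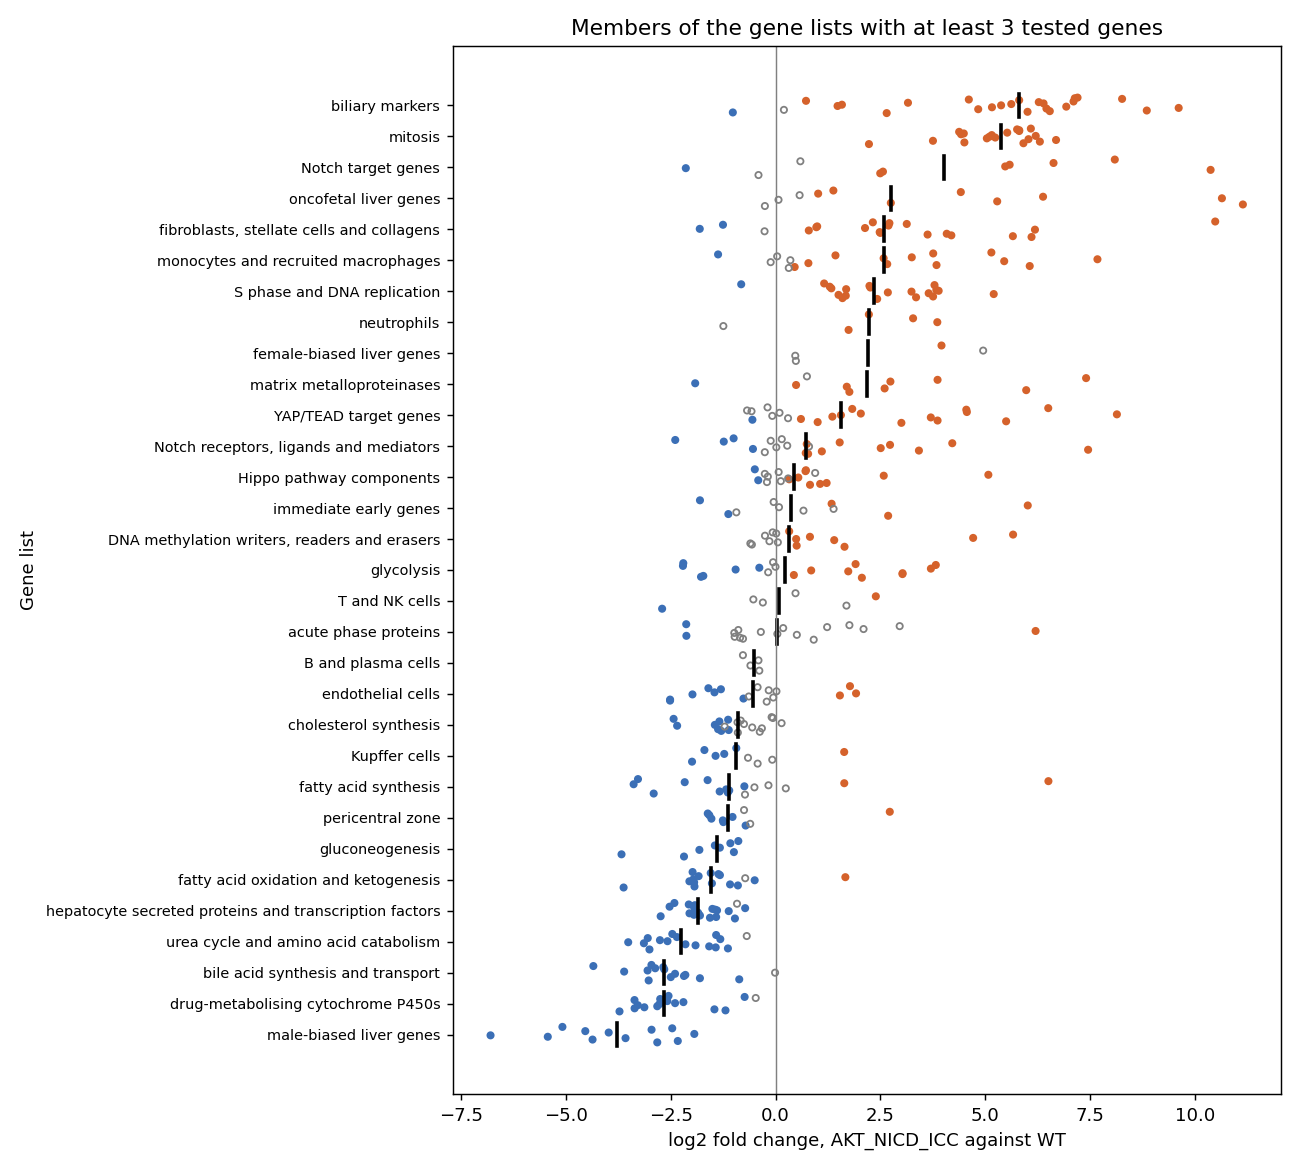
Log2 fold change (AKT_NICD_ICC against WT) of each tested member of the 31 gene lists with at least 3 tested genes; orange points rose, blue points fell and open grey points did not pass the edgeR test, and black bars are list medians. Medians run from -3.78 for male-biased liver genes to 5.81 for biliary markers.

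All 20 mitosis genes rose, with a median of 5.38 (camera adjusted p = 4.86e-09 at the preset correlation, adjusted p = 0.38 with an estimated correlation). Mki67, which encodes the proliferation marker Ki-67, went from 4.09 ± 0.918 to 190 ± 29.2 CPM (5.53, SE 0.22, adjusted p = 1.59e-07), and Ccnb2, a mitotic cyclin, rose by 5.04 (SE 0.22, adjusted p = 1.97e-07). Of 20 S phase and DNA replication genes 19 rose and 1 fell, with a median of 2.34 (camera adjusted p = 6.39e-06, adjusted p = 0.412 with an estimated correlation). The replicative helicase subunit Mcm6 rose by 3.84 and the ribonucleotide reductase subunit Rrm2 by 3.79. Tk1, thymidine kinase, fell by 0.82 on the log2 scale (SE 0.17, adjusted p = 0.00148), a value that was 0.01 with total counts (adjusted p = 0.958). Oncofetal genes, which are high in fetal liver, rose in 8 of 11 tested members, with a median of 2.75, or 3.34 to 3.51 without the filter, in the larger strand column and in thinned libraries (camera adjusted p = 0.0109, adjusted p = 0.38 with an estimated correlation, and adjusted p = 0.0580 with total counts). The imprinted long noncoding RNA H19 had 3 WT counts, all in replicate 2, and 156 ± 40.5 CPM in ICC, a ratio of 1681 (95% counting interval 575 to 8150). Its fitted log2 fold change of 10.65 (adjusted p = 3.02e-07) was 10.05 without WT replicate 1. Without WT replicate 2 and in the larger strand column WT had 0 counts, and H19 was at least 1081-fold and at least 874-fold higher. The imprinted gene Peg3 rose by 4.42 (SE 0.31, adjusted p = 2.01e-06). Afp, alpha-fetoprotein, named after its values were seen, had a log2 fold change of -0.25 (SE 0.33, adjusted p = 0.510). The 3 lists gave the same counts adjusted over the list alone.

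In fatty acid synthesis 10 of 16 genes fell (11 adjusted over the list alone) and 2 rose, with a median of -1.12 (camera adjusted p = 0.0163, adjusted p = 0.449 with an estimated correlation). Mlxipl, which encodes the glucose-responsive factor ChREBP, fell by 3.39 and Acacb, an acetyl-CoA carboxylase, fell by 2.91. Scd2, a stearoyl-CoA desaturase, rose from 6.13 ± 2.22 to 564 ± 245 CPM (6.51, SE 0.49, adjusted p = 2.92e-06). In cholesterol synthesis 8 of 19 genes fell (7 adjusted over the list alone) and none rose, with a median of -0.91 (camera adjusted p = 0.0109, adjusted p = 0.651 with an estimated correlation). Sc5d, a late enzyme of the pathway, fell by 2.43 and Insig1, a regulator of it, fell by 2.35. In glycolysis 9 of 18 tested genes rose and 6 fell, also when adjusted over the list alone, and the list did not pass (median 0.22, camera adjusted p = 0.71). Pkm and Pfkp, isoenzymes common outside the liver, rose by 3.82 and 3.71 (Pfkp by 2.64 in the larger strand column), and Slc2a2, the hepatocyte glucose transporter, fell by 2.20.

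Of 20 genes of fibroblasts, stellate cells and collagens 17 rose and 2 fell, with a median of 2.6 (camera adjusted p = 0.000696, adjusted p = 0.449 with an estimated correlation). Col4a1, a basement membrane collagen, went from 59.3 ± 2.00 to 1006 ± 117 CPM (4.08, SE 0.18, adjusted p = 1.97e-07). Lox, which cross-links collagen, rose by 6.19, or 6.84 without WT replicate 2 and 7.48 in the larger strand column, where WT had 3 counts. Lrat, the retinol-storing enzyme of quiescent stellate cells, fell by 1.81 on the log2 scale (SE 0.33, adjusted p = 0.000725). In matrix metalloproteinases 8 of 10 genes rose and 1 fell, and the list did not pass (median 2.18, camera adjusted p = 0.0629). It passed without the count filter (adjusted p = 0.0487). Mmp2 and Mmp14 rose by 2.74 and 1.70, and Mmp19 fell by 1.92. Of 16 endothelial genes 7 fell and 3 rose (median -0.53, camera adjusted p = 0.104). With total counts that median was 0.27, below the median of all genes under that scaling (0.93), and the list passed (adjusted p = 0.0125). Dnase1l3, high in liver sinusoidal endothelium, fell by 2.52 and the VEGF receptor gene Kdr fell by 1.98, whereas the VEGF receptor gene Flt1 rose by 1.53. Counts adjusted over the list alone were the same for these 3 lists.

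In the list of monocytes and recruited macrophages 12 of 17 genes rose and 1 fell, with a median of 2.58 (camera adjusted p = 0.00618, adjusted p = 0.449 with an estimated correlation). Cx3cr1, a chemokine receptor, rose by 5.45, or 6.06 without WT replicate 1 and 6.45 in the larger strand column, where WT had 3 counts, and Trem2, a macrophage receptor, rose by 5.15. The mannose receptor gene Mrc1 fell by 1.37. Of 9 genes of Kupffer cells, the resident macrophages of liver, 5 fell and 1 rose, and the list did not pass (median -0.94, camera adjusted p = 0.107) except with total counts (median -0.12, adjusted p = 0.0125). Clec4f and Timd4 had log2 fold changes of -1.43 and -1.70, calls lost with total counts (adjusted p = 0.0619 and 0.0520), and Marco rose by 1.64, a call lost with limma-voom (adjusted p = 0.0524). Counts adjusted over the list alone were the same for both lists. Of 5 tested neutrophil genes 4 rose and none fell (1 fell adjusted over the list alone), and the list did not pass (median 2.23, camera adjusted p = 0.382). Csf3r, a cytokine receptor gene, rose by 1.74. Retnlg had 1 WT count, in replicate 3, and a ratio of 17.6 (95% counting interval 3.05 to 705), with a fitted log2 fold change of 3.86 (adjusted p = 0.00892) that was 2.88 with limma-voom. Without that library WT had 0 counts, and Retnlg was at least 4.21-fold higher.

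Lymphocyte lists were little measured. Of 6 tested genes of T and NK cells Lck rose by 2.39 (adjusted p = 0.00252), or 3.64 without WT replicate 1, and Cd4 fell by 2.71 (adjusted p = 5.95e-05), the same adjusted over the list alone. The list did not pass (camera adjusted p = 0.71), and its median of 0.09 and the direction of its test, downward, differed in sign. None of 4 tested genes of B and plasma cells passed edgeR's test, either over all genes or adjusted over the list alone (median -0.50, or 0.31 with total counts, camera adjusted p = 0.38). Of 17 acute phase genes 1 rose and 2 fell (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.412), with a median of 0.04 and a test directed downward. Lcn2, lipocalin 2, went from 5.28 ± 3.42 to 393 ± 184 CPM (6.20, SE 0.58, adjusted p = 9.64e-06), or 6.89 without WT replicate 2. Hamp, hepcidin, fell by 2.13 (SE 0.35, adjusted p = 0.000376). Saa4, a serum amyloid gene, had a log2 fold change of -2.13 (adjusted p = 0.0178), which was -3.09 without ICC replicate 4, -2.73 with limma-voom, and lost its call without WT replicate 2 (adjusted p = 0.0505) and with total counts (adjusted p = 0.0529). Of 10 immediate early genes 3 rose and 2 fell, also when adjusted over the list alone (median 0.37, camera adjusted p = 0.614). Ier3 and Atf3 rose by 6.02 and 2.69, and the phosphatase gene Dusp1 fell by 1.13, a call lost with total counts (-0.29, adjusted p = 0.191).

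The 3 lists with fewer than 3 tested genes had no list test, and their gene counts were the same adjusted over the list alone. Alas2, of heme synthesis, was the tested gene of the red blood cell list and fell by 3.89 (SE 0.43, adjusted p = 2.96e-05). The hemoglobin genes of that list had 0 counts in each of the 8 libraries, which says that the counting did not measure them. Fabp4 and Cidec, from the adipocyte list, had log2 fold changes of 1.37 (adjusted p = 0.00110) and 1.32 (adjusted p = 0.0184). Cidec lost its call with limma-voom (adjusted p = 0.106) and without WT replicate 1 or 3 (adjusted p = 0.0758 and 0.0519). From the pancreatic acinar list, Cela1 fell by 3.38 (SE 0.10, adjusted p = 7.14e-08). Cela2a had a log2 fold change of -1.12 (adjusted p = 0.0459), whose call was lost in 12 of 19 alternatives, including in the larger strand column (-0.26) and without WT replicate 1, 2 or 3 (adjusted p = 0.148, 0.0762 and 0.0920) and without ICC replicate 1, 2 or 5 (adjusted p = 0.0785, 0.0826 and 0.0762).

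**Figure D3:**
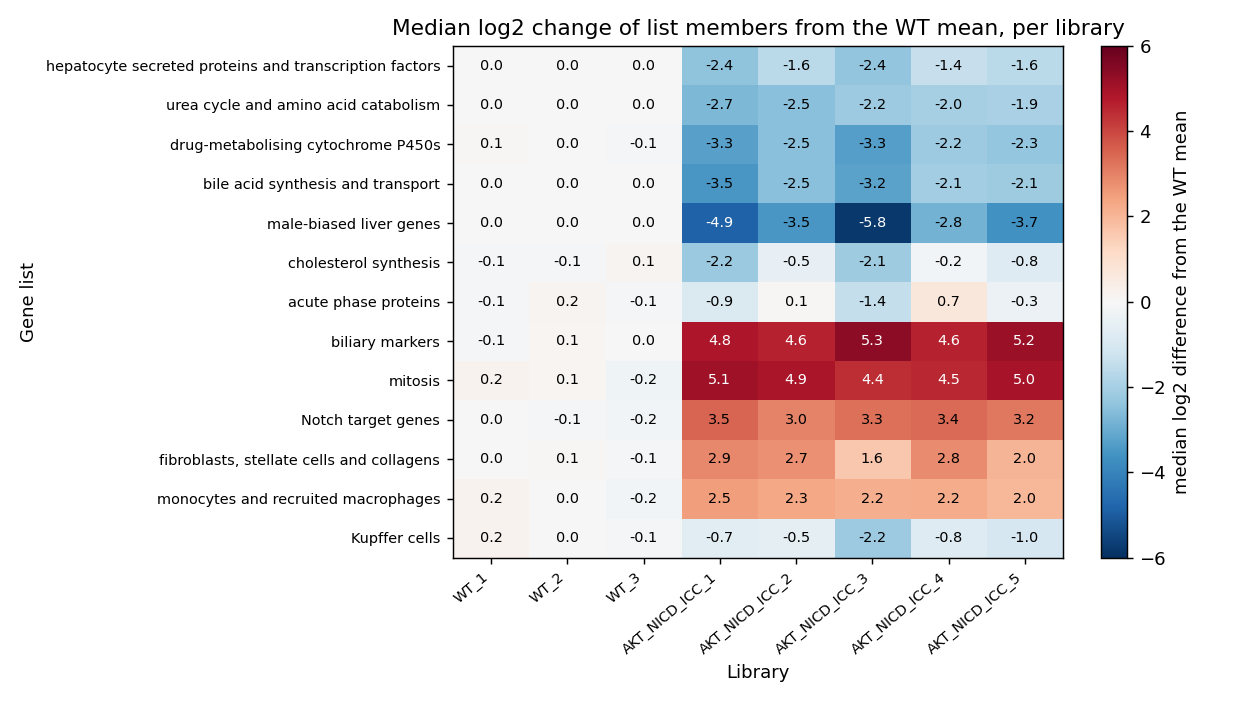
Median over list members of the log2 difference from the WT mean, per library, for 13 gene lists; columns are the 8 libraries and the colour scale is in log2 units of CPM plus 0.5, so values are smaller than fitted changes of genes near 0 in WT. ICC replicates 1 and 3 were lowest for secreted hepatocyte proteins (-2.40 and -2.39) and male-biased genes (-4.86 and -5.77), and ICC replicate 4 was highest (-1.39 and -2.82).

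Of the 31 lists tested, 18 passed with camera at the preset correlation, 8 higher and 10 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.38 and 1 list had an unadjusted p under 0.05. By fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, 24 lists passed, and 28 passed its test of change in either direction. Groupings of the same 8 libraries gave 18 or more passing lists in 9 of 56 splits, the real one included. In the others of these splits the WT libraries stayed mostly or wholly in 1 group, so they do not show what chance gives.

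Library measures also parted the groups, so they moved with each gene group described here. Reads that did not map were 9.32% ± 2.24 of all reads in WT (SD, n = 3) and 2.41% ± 0.485 in ICC (SD, n = 5). The exact two-sided permutation p was 0.0179, the smallest that 56 splits allow. This share was not among those planned, and its p-value is unadjusted. The 20 most abundant genes took 25.2% ± 1.95 of gene counts in WT and 16.2% ± 2.79 in ICC, and reads in more than 1 gene were 1.60% ± 0.138 and 1.89% ± 0.0702. Both had an exact permutation p of 0.0179, or 0.0536 after Benjamini-Hochberg adjustment over 6 shares. Reads in no gene (10.1% and 9.0%, exact p = 0.143) and multimapping reads (5.64% and 5.41%, exact p = 0.589) did not pass. The labels give no batch, so a batch that followed the groups cannot be told apart from them. WT replicate 3 held 68929 CPM of Rn45s, the precursor of ribosomal RNA, against 1442 to 2626 CPM in the other 7 libraries, and 6413 CPM of Lars2 against 78.8 to 146 CPM. Without Rn45s, Lars2 and Mir6236, an alternative chosen after seeing the data, the calls were 5423 higher and 4366 lower.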

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

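The tests of hepatocyte loss, of a female pattern, of pancreatic tissue and of a wrong label were chosen after the result was seen. The tests of other splits, of kidney and bladder tissue and of ribosomal RNA were chosen before their own values were seen. Those of kidney and bladder tissue and of ribosomal RNA address patterns already found in these data. The test of a female pattern was changed after its values were seen, from the tested members (median 2.21) to all members, and decides only where most of these pass the count filter.

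In 5 of 112 results the highest or lowest ICC library lay far from the other 4, where 5.6 are expected by chance. The gap as a share of the range was 0.884 for Cyp4a14 (ICC replicate 3, 429 CPM against 113 CPM in the next). It was 0.719 for Ajuba (ICC replicate 2, 98.8 against 77.6 CPM). It was 0.842 for Cd4 (ICC replicate 5, 1.10 against 0.657 CPM). It was 0.765 for Cela1 (ICC replicate 3 lowest, 4.07 against 4.70 CPM). It was 0.781 for Saa4 (ICC replicate 4, 282 against 78.2 CPM).

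The 4 gene counts were 5423 higher, 4368 lower, 3856 higher by over 2-fold and 2131 lower by over 2-fold. Each was reached in 1 of 56 splits of the 8 libraries, the real one, which is the smallest share possible. The highest count of the other splits was 0. Each other split put WT and ICC libraries together in a group, which widens the spread within it. That 0 therefore cannot show how many calls chance gives, and no conclusion on chance is drawn. The 18 passing gene lists were reached in 9 of 56 splits, with up to 20 lists in another split. The other splits that reached 18 kept the WT libraries mostly or wholly in 1 group. They hold much of the difference between WT and ICC, so the test cannot decide whether chance gives that number of lists.

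Hepatocyte genes were lower by unequal amounts: the male-biased list lay below the secreted protein list by a median of -2.04 (log2) over the ICC libraries, from -1.43 to -3.38. Loss of hepatocytes alone, with the remaining ones unaltered and no other cell making these transcripts, needs 1 common fall, which these values do not show. The male-biased list was already known to have the lowest median of the 31 lists, so the gap is a description and no independent test. Where tumour cells make part of the secreted list, loss of hepatocytes alone stays open. A female pattern in place of the male one stays open: the median over all 12 female-biased members was at most 0.650 CPM in an ICC library and 1 of the 4 members tested, Hao2, rose. All mice were male, so no library shows what level that pattern needs, or that the 8 members under the count filter, some with close paralogs, can be counted. The tumour model itself, which the design names, could act on male-biased genes and was not tested apart from these.

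Gp2, Upk3a and Umod, known from pancreas, bladder and kidney, were at 1824, 166 and 23.7 CPM in ICC and at 0 counts in WT. Tissue of these organs would bring its other abundant transcripts. The highest list median in an ICC library was 0.137 CPM for pancreas, 0.0564 CPM for kidney and 0.132 CPM for bladder, with 0 counts of Cpa1, Cpb1, Pnlip, Kap and Slc34a1. Napsa, the 1 tested gene of the kidney list, rose to 2.39 CPM (2.93, edgeR adjusted p = 0.000415). Upk1b and Upk3b of the bladder list reached 2.24 and 3.52 CPM in an ICC library and did not pass. The low medians argue against all 3 tissues as the source, so far as the list members can be counted. No library of these organs shows that members at 0 can be. Expression by the tumour may account for Gp2, Upk3a and Umod, as a hypothesis found and examined in the same data.

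Rn45s, Lars2 and Mir6236 were far above all other libraries in WT replicate 3 (68929, 6413 and 50.6 CPM). Rn45s, the precursor of ribosomal RNA, took 4.71% of gene counts there, against 0.165% to 0.349% in the other libraries. More of this RNA was thus counted in that library. Whether ribosomal RNA also accounts for Lars2 and Mir6236 stays open: 0 stretches of 25 bases of Lars2 occur in the 356 ribosomal RNA transcripts searched. The bound set beforehand for that count was wrong, since the longest nuclear transcript among them has 1849 bases and the large subunit RNA was therefore not searched. A wrong label or a mixture with tumour is argued against, since this library's lowest correlation with a WT library exceeded its highest with an ICC library by 0.154.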

How the results depend on the processing

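The alternative without Rn45s, Lars2 and Mir6236 was chosen after seeing the data; all others were planned. Of 2008 comparisons of 106 named genes with an alternative, 1967 kept direction and side of the threshold, 32 lost their call, 3 gained a call and 6 reversed, and 87 genes kept both throughout. For the 31 lists these were 521 of 556, with 20 lost, 3 gained and 12 reversed; 7 lists kept both throughout. Leaving out single libraries gave 4964 to 5378 genes higher and 3930 to 4489 lower, 3663 to 3859 and 2000 to 2321 by over 2-fold, and 18 lists each time. DESeq2 gave 5936 and 4465, upper-quartile scaling 6111 and 3656, no filter 5702 and 4264, and thinning to the smallest library, which tests depth, 5243 and 4257. DESeq2 and limma-voom were not run for the lists.

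With total counts only, 9699 genes were higher and 1601 lower, 6705 and 820 by over 2-fold, against 5423, 4368, 3856 and 2131 with TMM. That scaling raised the median of all genes by 0.82, and it reversed Yap1 (0.31), Tead3 (0.57), Dnmt3b (0.25), Asap1 (0.28), Mob1b (0.41), Tk1 (0.012), the endothelial list (0.27) and the list of B and plasma cells (0.31). Relative to that shift these 8 values are negative. With an estimated inter-gene correlation 0 lists passed with camera, 1 had an unadjusted p under 0.05, and fry passed 24. The median of the T and NK cell list reversed without the filter (-0.015) and ranged from -0.17 to 0.64 with single libraries left out; that of the acute phase list ranged from -0.33 to 0.19. In the larger strand column the difference in reads in no gene reversed (2.88 percentage points, exact p = 0.0179) and that in ambiguous reads was 0.0780 (exact p = 0.0536); with single libraries left out the former ranged from -1.61 to -0.459. The cause was not tested.

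The replicate numbers showed no sign of pairing the samples: deviations of same-numbered libraries correlated at 0.0206, -0.0149 and 0.0335, and 1 of 3 WT libraries correlated best with its own number. The labels state no pairing, and these few correlations cannot exclude 1. With the replicate block 5062 genes were higher and 4069 lower (3828 and 2365 by over 2-fold) and 19 lists passed. Under the block Alb (adjusted p = 0.0582), Retnlg (adjusted p = 0.0538) and Cela2a (adjusted p = 0.0790) had no call, the metalloproteinase list passed (adjusted p = 0.0123), and the medians of the T and NK cell list (-0.65) and the acute phase list (-0.66) reversed; no other call of a named gene or list changed. On the fold scale the block moved 9 named genes and 2 list medians by over 1.5 times, given here as log2 values under the block. The genes were Hsd3b5 (-9.18), Car3 (-8.84), Pitx3 (-7.79), G6pc (-4.31), Sc5d (-3.18), Insig1 (-3.10), Mmp19 (-2.55), Alas2 (-4.70) and Saa4 (-3.48). The medians were those of the cholesterol synthesis (-1.72) and male-biased (-4.52) lists.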

Other observations

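The 8 gene lists of the next 2 paragraphs and the test of Dnmt1 were chosen after the results were seen. Cdkn1a, Inhbb, Lama5, H19, Igf2, Peg3, Fstl1 and Rplp0 had been looked at before, as had Dlk1, Plagl1, Tgfb2, C6 and C8b in earlier lists. List p-values are adjusted over these 8 lists, the imprinted list included. Since the lists followed results already seen, their p-values describe them and give no independent support.

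Laminins and integrins, which anchor epithelium to basement membrane, rose in 16 of 19 tested genes and fell in 2, with a median log2 fold change of 2.59 (camera adjusted p = 0.000234, adjusted p = 0.0302 with an estimated correlation). Lama5 rose from 4.36 ± 0.206 to 193 ± 48.3 CPM (5.46, edgeR adjusted p = 2.68e-07), and Itgb4 rose by 7.79, while Lama3 fell by 3.20 on the log2 scale. All 8 cyclin-dependent kinase inhibitors rose (median 4.17, camera adjusted p = 0.000473, adjusted p = 0.0305 with an estimated correlation). Cdkn1a (p21) rose from 6.29 ± 3.64 to 171 ± 7.58 CPM (4.79, edgeR adjusted p = 1.28e-06), and Cdkn2a, at 0 counts in WT, was at least 78.9-fold higher. Imprinted genes expressed in fetal tissues rose in 12 of 14 tested members (13 adjusted over the list alone; median 3.39, or 3.04 with the bound), with Igf2 at 6.38 and Meg3 at 3.82. H19, Igf2, Dlk1, Peg3 and Plagl1 had already been called higher in the oncofetal list, so a test of this list gives no independent support and its p-value is left out.

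TGF-beta and activin genes rose in 12 of 17 members and fell in 2 (median 1.67, camera adjusted p = 0.00994, adjusted p = 0.0505 with an estimated correlation), with Tgfb2 at 6.51 and Inhbb at 5.87. Wnt ligands and secreted inhibitors rose in 9 of 14 members and fell in 1 (median 3.54, or 3.15 with bounds, camera adjusted p = 0.00835, adjusted p = 0.04995 with an estimated correlation). The Wnt list's last value lies at the threshold, and its adjustment includes the imprinted list, whose test was set aside, so no conclusion is drawn from it. Wnt7b, at 0 counts in WT, was at least 92.4-fold higher, and Dkk3 rose by 6.67. Complement and coagulation factors fell in 22 of 23 members (median -1.82, camera adjusted p = 2.16e-06, adjusted p = 0.358 with an estimated correlation), with C3 the exception (-0.74, adjusted p = 0.0901). Of 24 ribosomal protein genes 7 rose and 1 fell, or 2 and 1 adjusted over the list alone (median 0.14, camera adjusted p = 0.402). Of 18 polycomb genes 7 rose, Ezh2 among them (1.98), and 2 fell (median 0.32, camera adjusted p = 0.430). The other 6 lists gave the same counts adjusted over the list alone.

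A hypothesis that Dnmt1 rose beyond genes expressed in dividing cells was set against the S phase and DNA replication list. Of its 20 genes 14 had a larger log2 fold change than Dnmt1 (1.64), so by fold change Dnmt1 did not stand out from this list. These values had been seen before the test was chosen, and a fold change also depends on the level in WT. The hypothesis is therefore not decided.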
